A study of Homo sapiens with 6 samples.

How the data were processed

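RNA sequencing of the human stellate cell line LX-2 was compared between 3 samples with control siRNA and 3 with PERK siRNA, all given palmitic acid and collected 24 h later. Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, RNA was purified with a column kit and libraries were made with a directional kit, which keeps strand. Whether the counting used strand, and the aligner, the counter and the annotation release, are not given in the sources used here. The genome build was hg38, per the submitters' processing notes.

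Each deposited table held 1 row for each of 21533 genes, of which 20049 were protein coding. The other 1484 rows had an exon length of 0 and held no reads in any sample. Per the file headers, the authors gave total exon reads and unique exon reads as counts per gene, and TPM. The deposited TPM equalled total exon reads divided by exon length and scaled to the constant TPM total, to within a largest relative difference of 7.1e-08, and was not tested. The tested counts were the total exon reads, as deposited. Of these reads 94.9 to 95.0% were placed uniquely per sample. Reads of genes with near-identical copies may be split by the authors' counting, so the uniquely placed share is given beside named genes where it was low, and the fit was repeated on unique exon reads, an alternative chosen after seeing the data.

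The main test was edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3) with TMM factors, the default expression filter, robust dispersion estimates and no covariate. It was applied to 12973 genes of the 16842 with a read, and p-values were adjusted by Benjamini and Hochberg at a threshold of 0.05. Fold changes are PERK siRNA against control siRNA on the log2 scale, and CPM are normalised by the TMM factors unless said to be of total exon reads. Depth was 17937141 to 19585872 total exon reads per sample. The 10 most abundant genes took 4.53 to 4.63% of reads in control samples and 5.34 to 5.38% in PERK siRNA samples. Replicates differed by more than sampling noise, with a chi-square per degree of freedom of 1.65 to 2.31 within groups and 62.0 to 67.4 between them, so no pair was taken for copies of one library. Separate libraries of one RNA can differ by more than counting noise too, so this does not show separate cultures.

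The gene lists, the tests, the alternatives other than those said to be added, and the rule for named genes were written before the data were examined. That rule took EIF2AK3 and the genes of the series title. It also took the 10 largest rises and 10 largest falls among genes past the threshold, with groups that did not overlap and a mean log2 CPM of at least 3. It further took up to 4 members of each list with the smallest adjusted p. A gene that the rule takes is not reported here. Genes outside the rule are said to have been chosen after their values were seen. The 27 lists covered the stress response, p38 and IL-1 signalling, NF-κB-linked and interferon genes, stellate cell state, secreted factors, metabolism, cell cycle, death, autophagy, histones, ribosomal and mitochondrial genes, and markers of other liver cell types. The 25 lists with at least 5 tested members were tested with camera (limma 3.58.1), which compares a list with all other genes, at a preset correlation between genes of 0.01 and again with an estimated correlation, and with fry.

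Alternatives were median-ratio, upper-quartile or no scaling factors, no filter or at least 1 CPM in 3 samples, and DESeq2 (1.42.0) or limma-voom in place of edgeR. Others were non-robust dispersion, the replicate number as a block, leaving out each sample in turn, and stricter thresholds including a test against a 1.2-fold change. On data simulated from these samples, edgeR recovered 33 of 50 genes changed 1.2-fold, 44 of 50 changed 1.5-fold, 48 of 50 changed 2-fold and 49 of 50 changed 3-fold, and called 11 of 12630 unchanged genes. A simulated list of 30 genes changed 1.25-fold had a camera p of 1.2e-49 with the preset correlation, 7.2e-05 with an estimated one and 1.5e-08 by fry. These tests called 2, 0 and 5 of 100 random lists. Genes were simulated independently and most were unchanged, unlike in the data, where the estimated correlation of the ribosomal list was 0.86. The simulation therefore does not show how the list tests perform on these data, nor the rates of recovery and of false calls among single genes in them.

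Places of genes and sequences of transcripts came from the GENCODE v29 annotation of GRCh38, the same assembly as hg38, matched on Ensembl gene identifiers. Words of 7 bases were counted in the 3′ UTRs of 12813 tested genes in Python 3.11.15. The other 160 tested genes had no annotated 3′ UTR and were not searched. The association of 14599 words, each in at least 100 genes, with fold change was ranked in 6406 genes, and the leading words were then tested in the 6407 genes held out, with 100000 permutations. The permutations tested differences in means, while the differences printed are in medians. For the ranked words the means were adjusted for 3′ UTR length and GC content. For the joined word, and for TATTTAT beside the leading pair, they were not adjusted. The share of carriers expected from length was that of the 200 genes nearest in 3′ UTR length. The scan recovered 2 of 2 words planted in simulated data.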

Results

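Gene expression was measured by RNA sequencing in LX-2, an immortalised human hepatic stellate cell line. Stellate cells are the liver cells that store vitamin A at rest and lay down matrix when activated. The series asks what PERK does in these cells in the setting of liver cancer, and its title names p38δ MAPK and IL-1β as the axis of interest. PERK, encoded by EIF2AK3, is an endoplasmic reticulum stress sensor that phosphorylates eIF2α. In 3 samples the cells had received a control siRNA and in 3 samples an siRNA against PERK, and all 6 were collected 24 h after palmitic acid, a saturated fatty acid that can stress the endoplasmic reticulum. No sample without palmitic acid was analysed here, so every difference reported is one of siRNA in lipid-treated cells. The control samples held 18560051 to 19585872 exon reads and the PERK siRNA samples 17937141 to 19535253. A count of 3 reads, taken as the detection floor, corresponded to 0.153 to 0.167 CPM, the reads of a gene scaled to the library's total, which covers counting error only. No label states that the samples of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

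The targeted mRNA was lower in every PERK siRNA sample. EIF2AK3 (ENSG00000172071; chromosome 2, 88556741 to 88627576, minus strand, GRCh38), counted over its exons, stood at 12.9, 13.0 and 13.9 CPM in the control samples and at 4.37, 4.96 and 5.51 CPM in the PERK siRNA samples. The group means were 13.3 ± 0.54 and 4.95 ± 0.57 CPM (SD, n = 3 each), so that 37.3% of the control level remained. The log2 fold change was -1.42 (SE 0.10), with an adjusted p of 3.0e-13 by edgeR's quasi-likelihood test.

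Both genes named in the title's axis were lower as well. IL1B, which encodes the inflammatory cytokine IL-1β (ENSG00000125538; chromosome 2, 112829751 to 112836903, minus strand), fell from 64.4 ± 2.90 to 20.3 ± 2.83 CPM (SD, n = 3 each), a log2 fold change of -1.67 (SE 0.07, adjusted p = 2.3e-11). MAPK13, which encodes p38δ (ENSG00000156711; chromosome 6, 36127809 to 36144524, plus strand), fell from 2.69 ± 0.15 to 1.02 ± 0.16 CPM (SD, n = 3 each), a log2 fold change of -1.39 (SE 0.22, adjusted p = 2.8e-06). MAPK13 was scarce, with 47 to 54 reads per control sample and 16 to 23 per PERK siRNA sample. Among the other p38 genes, MAPK14, encoding p38α, was the most abundant at 74.0 ± 1.71 CPM in controls and 71.6 ± 0.39 CPM with PERK siRNA (SD, n = 3 each), a difference that did not pass the test (log2 fold change -0.05, SE 0.04, adjusted p = 0.25). MAPK11, encoding p38β, did not pass either (0.18, SE 0.09, adjusted p = 0.078), but did without control sample 3 (adjusted p = 0.015) and on unique exon reads (adjusted p = 0.046), with adjusted p up to 0.41 under the other alternatives. MAPK12, encoding p38γ, was slightly higher (0.18, SE 0.06, adjusted p = 0.0091), a call lost with DESeq2 (adjusted p = 0.11) and without control sample 1 (adjusted p = 0.070).

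**Figure D1:**
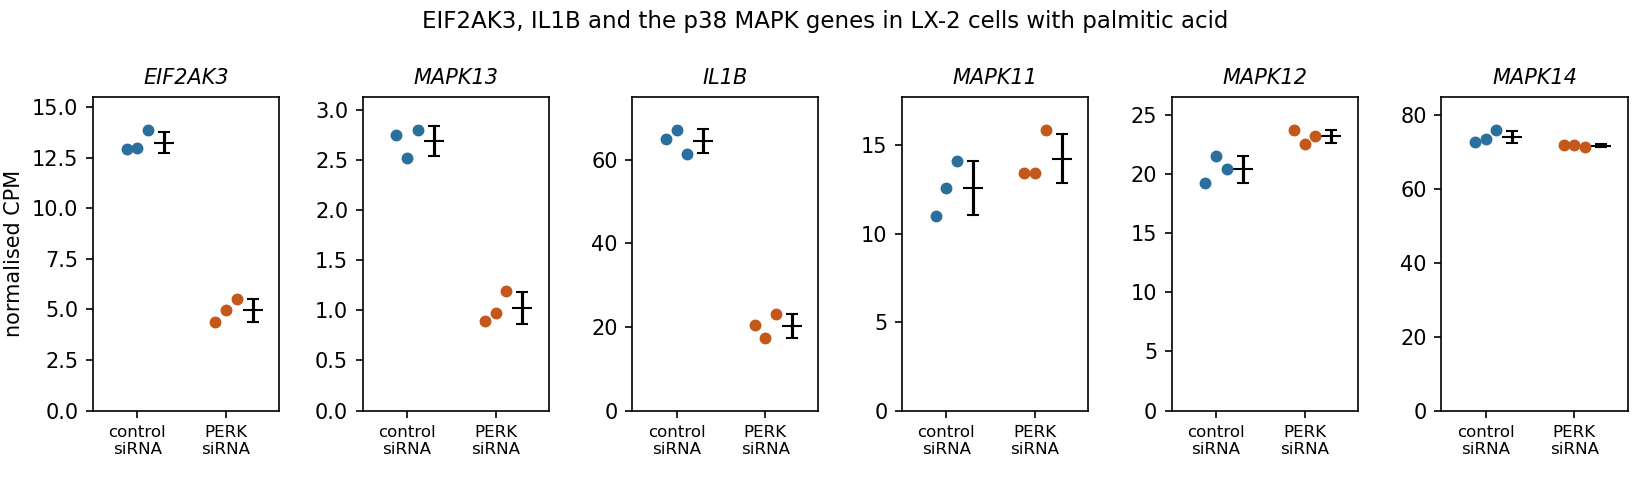
Each panel shows normalised CPM (vertical axis, starting at 0) of one gene in the 3 control siRNA samples (blue points) and the 3 PERK siRNA samples (orange points), with the mean and SD of each group as a black bar. The PERK siRNA samples lie at 4.37 to 5.51 CPM for EIF2AK3 and 17.4 to 23.0 CPM for IL1B, below all controls, while the MAPK14 samples of both groups lie between 71.1 and 75.8 CPM.

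The difference extended across the transcriptome. Of 12973 genes tested, 4469 were higher and 4545 lower with PERK siRNA at an adjusted p under 0.05, together 69.5%. Most of these changes were small: 528 genes were at least 2-fold higher and 498 at least 2-fold lower, and against a null of a 1.2-fold change 2345 were higher and 2344 lower. For 9310 genes (71.8%; chance gives 10%) all 3 samples of one group lay above all 3 of the other. Samples of a group correlated across genes with r of at least 0.992 in log2 CPM, against 0.965 to 0.966 between groups, where genes are not independent replicates, and the common biological coefficient of variation was 2.16%.

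Among genes with a mean log2 CPM of at least 3, the largest rise was that of GFRA1, a co-receptor for GDNF, from 11.7 ± 0.67 to 111.3 ± 1.70 CPM (SD, n = 3 each; log2 fold change 3.25, adjusted p = 3.8e-29). It was followed by the carboxypeptidase gene CPA4 (2.98), the pregnancy-specific glycoprotein gene PSG4 (2.63), WDFY1 (2.53) and the phosphoinositide phosphatase gene MTMR6 (2.49). ANKRD13A (2.43), RPS27L (2.33), ZNF268 (2.23), the sulfate transporter gene SLC26A2 (2.19) and ARHGAP18 (2.18) completed the 10 largest. For WDFY1, 69.6% of the reads were placed uniquely, for ZNF268 85.7% and for PSG4 91.3%, so part of their counts may be shared with similar genes.

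The largest fall among genes of that level was that of PTHLH, which encodes parathyroid hormone-related protein. It fell from 35.2 ± 3.13 to 3.15 ± 0.51 CPM (SD, n = 3 each; log2 fold change -3.47, adjusted p = 4.7e-21). ANGPTL4, an inhibitor of lipoprotein lipase, fell from 16.3 ± 2.87 to 1.47 ± 0.38 CPM (-3.46). VEGFA, the vascular endothelial growth factor, fell from 99.1 ± 4.42 to 14.5 ± 1.33 CPM (-2.77), and PLAU, the urokinase plasminogen activator, from 148.5 ± 3.04 to 21.6 ± 1.38 CPM (-2.78). The remaining large falls were those of PLEKHG4B (-2.98), the kinase gene CILK1 (-2.92), the protease-activated receptor gene F2RL1 (-2.84), SCG2 (-2.83), the metalloproteinase gene ADAMTS15 (-2.75) and the cystatin gene CST1 (-2.65). Of the exon bases of PLAU, 28.7% overlap another protein-coding gene, and 89.9% of the CST1 reads were placed uniquely.

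Most NF-κB-linked genes measured were lower. Of 26 tested members of the list of NF-κB-linked cytokines and chemokines, 23 fell and 2 rose, with a median log2 fold change of -0.97. Besides cytokines and chemokines, that list holds NF-κB subunits, inhibitors and other genes linked to NF-κB. CXCL1, a neutrophil chemokine, fell from 20.7 ± 1.66 to 5.50 ± 0.60 CPM (SD, n = 3 each; -1.90), CCL2, a monocyte chemokine, from 26.0 ± 1.22 to 8.78 ± 1.21 CPM (-1.57), and the mitochondrial superoxide dismutase gene SOD2 (-0.93) and the NF-κB subunit gene RELB (-0.98) fell too. CXCL8 (-2.15) fell, as did the scarce IL6 (-1.81, from 1.31 ± 0.51 to 0.37 ± 0.18 CPM; SD, n = 3 each). The NF-κB inhibitor gene TNFAIP3 (0.62) and the scarce CCL5 (0.86, from 1.46 ± 0.23 to 2.65 ± 0.37 CPM; SD, n = 3 each) rose, and CSF1 did not pass the test (0.05, adjusted p = 0.40). These 5 genes were chosen after their values were seen. The list lay below other genes by camera (adjusted p = 4.5e-05), but the call was lost with an adjusted p of 0.60 with an estimated correlation. In the IL-1 family and inflammasome list, 8 of 17 tested members fell and 5 rose, and the list did not pass the set test (adjusted p = 0.51). Besides IL1B, the falling members included CASP1, the protease that matures IL-1β (-1.32, with 91.8% of reads placed uniquely), and the IL-1 receptor-associated kinase genes IRAK2 (-1.25) and IRAK1 (-0.29). IL1A, chosen after its values were seen, fell as well (-2.58, from 2.16 ± 0.53 to 0.36 ± 0.13 CPM; SD, n = 3 each).

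The kinases around p38 moved both ways. Of 20 tested members of the p38 list, 6 rose and 7 fell (camera adjusted p = 0.93). MAP2K4, a kinase upstream of p38 and JNK, fell (-1.04), as did MAP3K5 (-0.54), whereas MAPKAPK3, a p38 substrate kinase (0.62), and MAP3K7 (0.56) rose.

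Genes of the endoplasmic reticulum stress response were lower in part. In the list of chaperones and degradation factors of that compartment, 21 of 32 tested members fell and 4 rose, with a median of -0.23 (camera adjusted p = 0.010; adjusted p = 0.60 with an estimated correlation). PDIA4, a disulfide isomerase, fell from 327.2 ± 4.50 to 207.0 ± 2.18 CPM (SD, n = 3 each; -0.66), and the chaperone gene HSP90B1 (-0.58) and the translocon-associated SSR1 (-0.64) fell. The lectin chaperone gene CANX went the other way, from 643.7 ± 3.98 to 1341 ± 27.5 CPM (SD, n = 3 each; 1.06). The chaperone gene HSPA5 fell (-0.48), and MANF (0.23), SEL1L (0.28) and EDEM3 (0.23) rose. These 4 genes were chosen after their values were seen, and the EDEM3 call was lost with DESeq2 (adjusted p = 0.12) and without control sample 1 (0.075) or PERK siRNA sample 2 (0.11).

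Targets of ATF4 and CHOP, transcription factors downstream of eIF2α phosphorylation, gave 14 falls and 8 rises among 29 tested members (median -0.09). The list did not differ from other genes past the threshold by camera (adjusted p = 0.51), while by fry, which does not compare it with other genes, it moved down (adjusted p = 0.0019). VEGFA, DDIT4 (from 50.3 ± 1.81 to 25.0 ± 1.23 CPM; SD, n = 3 each) and the pseudokinase gene TRIB3 (-0.83) fell, while KLHL24 rose (1.68). ATF4 itself was higher (0.38, adjusted p = 1.1e-10) and DDIT3, encoding CHOP, was lower (-0.50, adjusted p = 0.00012). Both were chosen after their values were seen. Of the DDIT3 reads 85.4% were placed uniquely, and 12.8% of its exon bases overlap another protein-coding gene. The list of eIF2α, its kinases and phosphatase subunits, the subunits of its exchange factor eIF2B and the co-chaperone gene DNAJC3 gave 6 falls and 3 rises among 13 (camera adjusted p = 0.52). Of its 6 kinases and phosphatase subunits 3 fell, EIF2AK3 itself, EIF2AK2, the kinase PKR (-0.59), and PPP1R15B (-0.57), and EIF2S1, encoding eIF2α, rose (0.32). The phosphatase subunit gene PPP1R15A (0.26) and the kinase gene EIF2AK1 (0.09), chosen after their values were seen, rose too. The EIF2AK1 call was lost with DESeq2 (adjusted p = 0.057) and without PERK siRNA sample 2 (0.065), and 11.9% of its exon bases overlap another protein-coding gene. The other falls were those of EIF2B3 (-0.29), EIF2B5 (-0.15) and DNAJC3 (-0.21), chosen after their values were seen, and the EIF2B5 call was lost with DESeq2 (adjusted p = 0.12) and without PERK siRNA sample 2 (0.18). Of 24 tested genes of amino acid synthesis and transport, 11 fell and 10 rose (camera adjusted p = 0.52). The amino acid transporter genes SLC38A1 (-0.75), SLC7A5 (-0.86), SLC1A5 (-0.44) and SLC3A2 (-0.39) were among those that fell. Cytosolic aminoacyl-tRNA synthetases gave 11 falls and 6 rises among 21 (camera adjusted p = 0.35), with XPOT, a tRNA export factor gene (-0.59), MARS1 (-0.44), YARS1 (-0.41) and TARS1 (-0.39) lower.

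Most glycolytic and hypoxia-responsive genes measured were lower. Of 24 tested members, 20 fell and 2 rose, with a median of -0.46 (camera adjusted p = 0.00018; adjusted p = 0.60 with an estimated correlation). The glucose transporter gene SLC2A3 fell from 61.7 ± 1.44 to 23.2 ± 0.67 CPM (SD, n = 3 each; -1.41) and the lactate dehydrogenase gene LDHA from 800.3 ± 11.3 to 513.9 ± 15.7 CPM (-0.64). PGAM1, a glycolytic mutase gene, fell by 0.86 on the log2 scale. Only 73.5% of the PGAM1 reads and 85.7% of the SLC2A3 reads were placed uniquely. The 2 rising members, BNIP3L (0.75) and ADM (0.81), were chosen after their values were seen.

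More apoptosis regulators fell than rose. Of 24 tested BCL2 family and death receptor genes, 13 fell and 4 rose, with a median of -0.38 (camera adjusted p = 0.037; adjusted p = 0.60 with an estimated correlation). The falling members act in opposite directions: PMAIP1 (-1.26) and BCL2L11 (-1.35) encode the pro-apoptotic proteins NOXA and BIM, and MCL1 (-0.60) and BIRC2 (-0.99) encode anti-apoptotic proteins. BCL2 (0.98), CFLAR (0.46), BOK (0.32) and BAX (0.29) rose and were chosen after their values were seen. Among p53 targets, 10 of 24 rose and 7 fell (camera adjusted p = 0.84), with CCNG1 higher (1.31) and the cell cycle inhibitor gene CDKN1A (-1.20) and AEN (-0.59) lower. Of 39 cell cycle genes, 20 fell and 13 rose (camera adjusted p = 0.58), with the replication helicase subunit gene MCM3 (-0.96) and E2F1 (-0.84) lower and CDK2 (1.30) and the mitotic kinase gene PLK1 (0.57) higher.

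Contractile and matrix genes of activated stellate cells split evenly, with 18 rises and 18 falls among 40 tested members (camera adjusted p = 0.89). The actin-binding gene TAGLN rose from 52.3 ± 0.18 to 171.6 ± 1.51 CPM (SD, n = 3 each; 1.71), although only 61.3% of its reads were placed uniquely and 18.4% of its exon bases overlap another protein-coding gene. The myosin light chain gene MYL9 (0.87) and the collagen crosslinking gene LOX (0.90) rose, while the collagen gene COL3A1 fell from 388.3 ± 15.4 to 208.9 ± 2.62 CPM (SD, n = 3 each; -0.89). ACTA2, encoding α-smooth muscle actin, rose (1.95), and COL1A1 did not pass the test (0.01, adjusted p = 0.58; 2910 ± 77.7 and 2940 ± 13.3 CPM; SD, n = 3 each). Both were chosen after their values were seen. Of 9 tested quiescence genes, 5 fell and 4 rose (camera adjusted p = 0.83). HGF, the hepatocyte growth factor gene, fell (-2.47) from 1.70 ± 0.09 to 0.31 ± 0.18 CPM (SD, n = 3 each), and ADIPOR1 fell (-0.39), while GATA4 (0.54) and LHX2 (0.53) rose. Of 26 secreted growth factors, 11 rose and 9 fell (camera adjusted p = 0.61). MDK (0.98) and IGFBP5 (0.90) rose, and WNT5A fell (-0.79).

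Lipid metabolism moved in both directions. Genes of fatty acid oxidation and PPAR targets gave 9 rises and 10 falls among 25 (camera adjusted p = 0.97). HADHB, of mitochondrial β-oxidation (0.97), and the acyl-CoA synthetase gene ACSL1 (1.05) rose, and ACSL3 (-0.57) and ACAA2 (-0.53, with 84.0% of reads placed uniquely and 10.5% of exon bases overlapping another protein-coding gene) fell. Of 34 genes of sterol and fatty acid synthesis, 17 fell and 9 rose (camera adjusted p = 0.51). MSMO1, of cholesterol synthesis, fell (-0.69), and STARD4 (0.78) and ACACA (0.57) rose. Among NRF2 targets, 15 of 25 fell and 4 rose (camera adjusted p = 0.076). The thioredoxin reductase gene TXNRD1 fell from 499.9 ± 26.8 to 165.2 ± 2.30 CPM (SD, n = 3 each; -1.60), GSR, the glutathione reductase gene, fell (-1.47), TKT fell (-0.54), and the ferritin light chain gene FTL rose (1.18). In the autophagy and lysosome list 11 of 26 rose and 9 fell (camera adjusted p = 0.61). The lysosomal membrane genes LAMP1 (1.51) and LAMP2 (1.21) rose, and ATG16L1 (-1.24) and the cathepsin gene CTSL (-0.59) fell.

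The 3 fixed lists that lay above other genes were those of mitochondrially encoded, ribosomal protein and interferon-stimulated genes. All 13 mitochondrially encoded mRNAs rose, with a median of 0.30 (camera adjusted p = 0.0074; adjusted p = 0.75 with an estimated correlation), among them MT-CO1 (0.30) and MT-ND1 (0.45). Their share of all reads was 0.514 to 0.575% in the control samples and 0.659 to 0.673% in the PERK siRNA samples. Of the 34 ribosomal protein genes on the list 23 rose, and the median was only 0.09 (camera adjusted p = 0.014; adjusted p = 0.82 with an estimated correlation), led by RPLP2 (0.36) and RPL13 (0.34). RPL30, chosen after its values were seen, was the 1 member of the list that fell (-0.12). That list did not pass without control sample 2 (adjusted p = 0.060). The 43 tested ribosomal protein genes outside the list, counted after the results were seen, gave 21 rises and 8 falls (median 0.06) and did not pass (unadjusted camera p = 0.077, and 0.74 with an estimated correlation). Interferon-stimulated genes rose in 18 of 31 cases and fell in 4, with a median of 0.35 (camera adjusted p = 0.030; adjusted p = 0.75 with an estimated correlation). IFIT2 (0.90), BST2, encoding tetherin (0.51), and SAMD9 (0.39) rose, whereas the transcription factor gene IRF1 fell (-0.59). The other falling members, IRF7 (-0.64), ISG20 (-0.99) and OAS3 (-0.12), were chosen after their values were seen. The interferon call was lost without control sample 1 (adjusted p = 0.053), PERK siRNA sample 2 (0.055) or PERK siRNA sample 3 (0.058). Of 10 replication-dependent histones, 4 rose and 1 fell (camera adjusted p = 0.51). H2BC12 led them (0.88), with 45.7% of its reads placed uniquely.

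**Figure D2:**
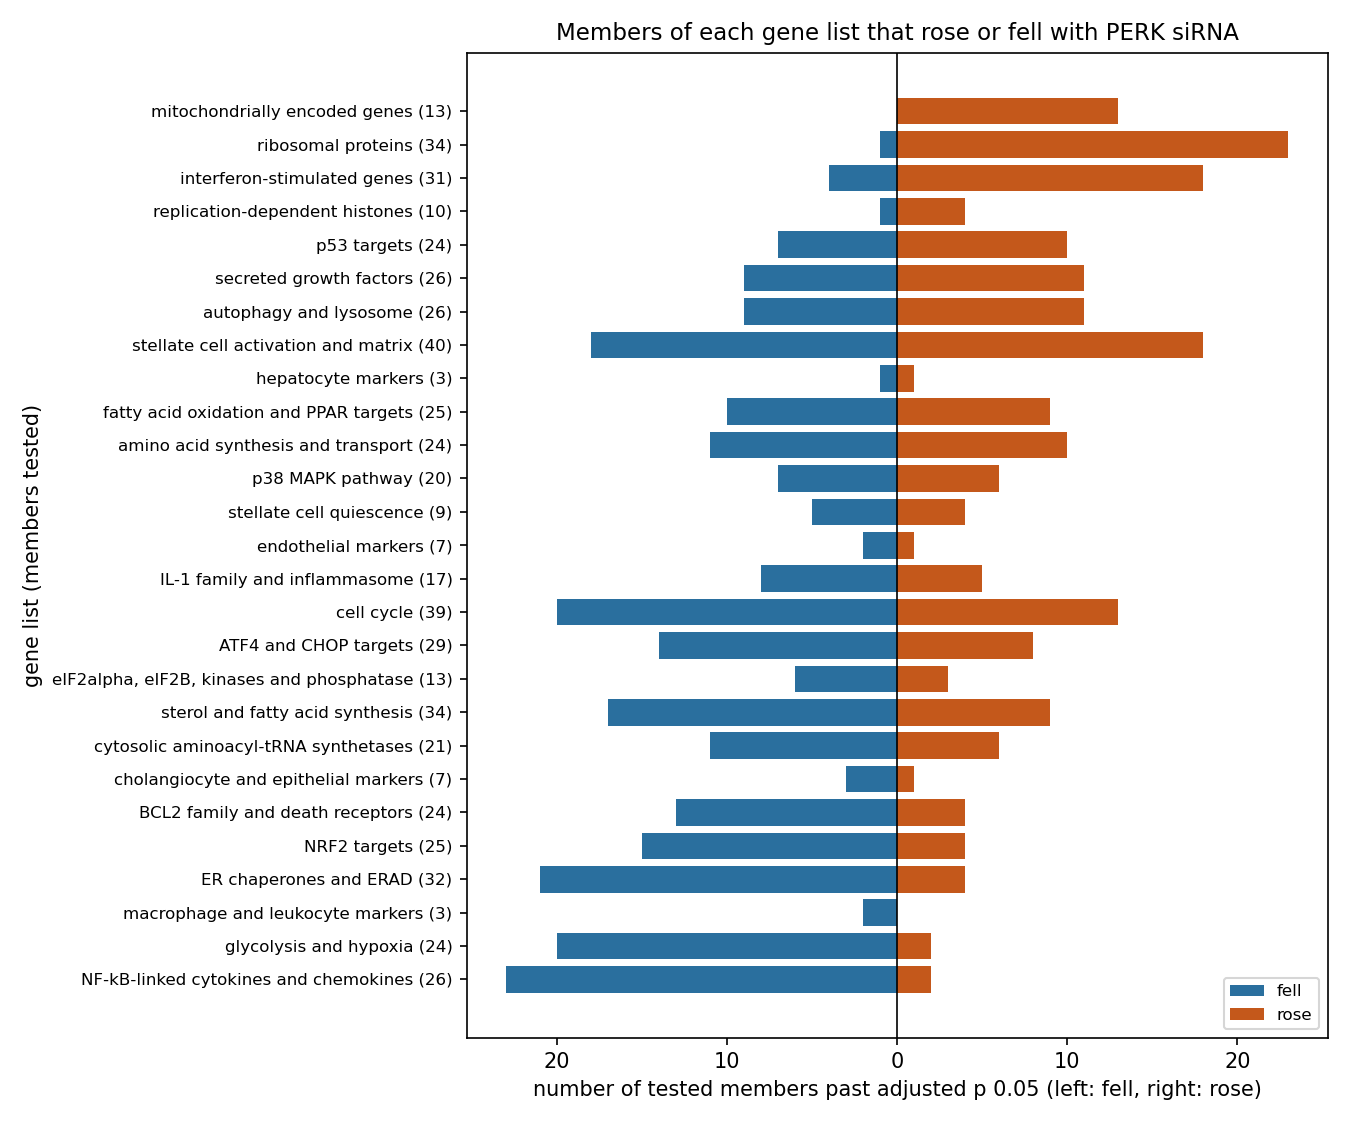
Horizontal bars give, for each fixed gene list, the number of tested members that fell (blue, leftward) or rose (orange, rightward) with PERK siRNA at an adjusted p under 0.05, and the number tested stands in parentheses. The list of NF-κB-linked genes has 23 falls and 2 rises, and the mitochondrially encoded list has 13 rises.

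**Figure D3:**
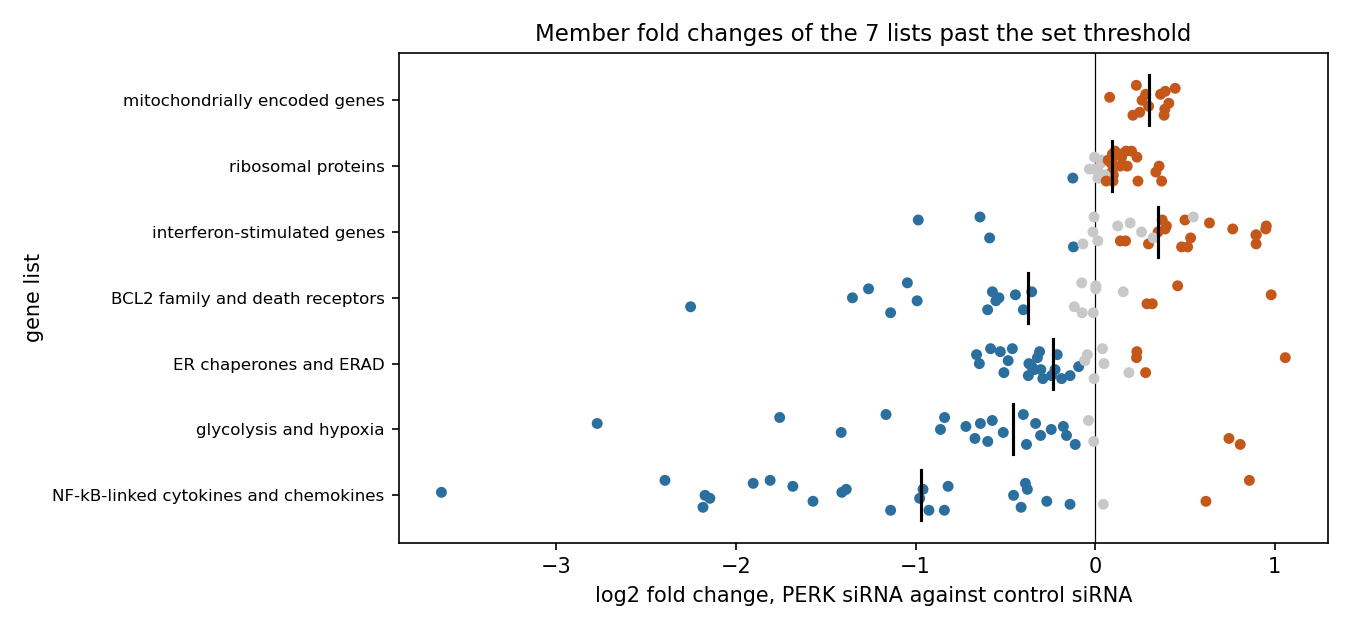
Each point is the log2 fold change (horizontal axis, PERK siRNA against control siRNA) of one tested member of the 7 lists past the set threshold, in orange where it rose, blue where it fell and grey where it did not pass, and black lines mark medians. The NF-κB-linked list has its median at -0.97, and the ribosomal list at 0.09.

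Some markers of other cell types were expressed, keratins most of all. Of 16 cholangiocyte and epithelial markers, 7 stood above 1 CPM in every sample, and the list summed to 829.0 to 836.8 CPM of total exon reads in the control samples and 752.4 to 780.3 in the PERK siRNA samples. Of these 7, all tested, 3 fell and 1 rose (camera adjusted p = 0.52). The keratin gene KRT8 stood at 363.1 ± 5.84 and 366.8 ± 9.27 CPM (SD, n = 3 each), did not pass the test (0.01, adjusted p = 0.62) and was chosen after its values were seen. KRT18 fell slightly, from 315.2 ± 5.47 to 293.9 ± 3.25 CPM (SD, n = 3 each; -0.10), as did KRT7 (-0.82) and SOX9 (-0.54). CD24 rose (0.24), a call lost with DESeq2 (adjusted p = 0.12) and without control sample 3 (0.062). EPCAM, KRT19 and CDH1, also on that list, had 4, 27 and 0 reads over the 3 control samples. Of 17 endothelial markers, 6 stood above 1 CPM in every control sample, and the list summed to at most 32.2 CPM of total exon reads in control and 21.6 in PERK siRNA samples. Of 7 tested, 2 fell and 1 rose (camera adjusted p = 0.51): PECAM1 fell (-3.80, from 8.95 ± 0.05 to 0.63 ± 0.11 CPM; SD, n = 3 each), ROBO4 fell (-0.89) and FLT1 rose (0.78). Hepatocyte and leukocyte lists had 3 tested members each, too few for a set test. Hepatocyte markers summed to 46.4 to 50.2 CPM of total exon reads in control and 82.4 to 84.7 in PERK siRNA samples. Most of it was CPS1, which rose (0.90, from 42.3 ± 1.91 to 79.2 ± 1.15 CPM, SD, n = 3 each), while ALB and APOA1 had 0 reads. The scarce ASGR1 fell (-0.75, from 1.49 ± 0.17 to 0.88 ± 0.23 CPM, SD, n = 3 each). Its adjusted p was 0.016 by edgeR and up to 0.12 under the alternatives. Leukocyte markers summed to 82.9 to 86.6 and 73.2 to 75.7 CPM of total exon reads, most of it the lysosomal membrane gene CD68, chosen after its values were seen, which did not pass the test (68.3 ± 1.29 and 65.9 ± 1.30 CPM; SD, n = 3 each; adjusted p = 0.20). Of the leukocyte markers, 2 fell: the receptor gene CSF1R from 5.03 ± 0.44 to 0.56 ± 0.25 CPM (-3.14) and CD14 from 9.90 ± 0.40 to 7.11 ± 0.24 CPM (-0.48; SD, n = 3 each). PTPRC, LYZ and TYROBP, abundant in leukocytes, had 17, 15 and 0 reads over the 3 control samples. The 8 scarce or undetected markers given only by their reads were chosen after their values were seen.

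Of the 25 lists with enough members, 7 passed the set test with the preset correlation. With an estimated correlation 0 passed after adjustment, and 1, the NF-κB-linked list, had an unadjusted p under 0.05 (p = 0.040). By fry, which asks only whether a list's genes move one way on balance, 22 passed. The median, mean and test differed in sign for 5 lists. For the p38 and IL-1 lists the median was positive (0.03 and 0.02) while the mean (-0.11 and -0.39) and the test pointed down. For secreted growth factors and fatty acid oxidation the mean was negative (-0.20 and -0.12) while the median (0.06 for both) and the test pointed up. For the stellate activation list the median was -0.02, the mean 0.06 and the test pointed up. Adjusted over the list alone, the counts of members that rose and fell were the same for all 27 lists except 3. Amino acid genes and aminoacyl-tRNA synthetases each had 12 falls, and histones had 0 falls.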

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

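The repeat on unique exon reads was chosen after seeing the data. No named gene and no list reversed its direction past the threshold under any alternative. Of 2463 comparisons of 154 named genes under 16 settings, 2441 stayed on their side of the threshold, 20 lost the call and 2, both of MAPK11, gained it. The calls lost were those of MAPK12, EDEM3, EIF2AK1, EIF2B5, ASGR1, CD24, H1-2 and H2BC5. Counts of genes higher and lower were 4321 to 4648 and 4359 to 4688 under the other scalings, 3639 and 3929 with DESeq2, 4475 and 4479 on unique exon reads, and 4198 to 4294 and 4334 to 4427 with 1 sample left out. Of 8751 genes called on both total and unique reads, 8749 had the same sign. Requiring a 2-fold change left 528 higher and 498 lower, and testing against a 1.2-fold change left 2345 and 2344; the stricter criterion itself accounts for the smaller counts. The EIF2AK3 log2 fold change ranged from -1.50 to -1.34, that of MAPK13 from -1.52 to -1.31 and that of IL1B from -1.77 to -1.57. The number of lists past the threshold was 7 with the preset correlation, 0 with an estimated correlation and 22 by fry. For the NF-κB-linked list the adjusted p was 0.60 with an estimated correlation. Its estimate was 0.086, against the preset 0.01. The other lists past the preset threshold had estimates of 0.019 (apoptosis regulators) to 0.86 (ribosomal proteins). Camera also weakened for the eIF2α (-0.0038), amino acid (-0.026) and endothelial (-0.077) lists, whose estimates lay under the preset. It strengthened slightly for the p38 (-0.0058) and fatty acid oxidation (-0.033) lists. Higher correlation thus did not account for all of the weakening across lists. With an estimated correlation camera also uses the few residual degrees of freedom of the 6 samples. With a preset one it uses degrees of freedom set by the number of genes. An adjusted p with an estimated correlation therefore reflects the small number of samples too, and the 2 parts were not separated. With 1 sample left out, 6 to 8 lists passed. NRF2 targets passed without a filter (adjusted p = 0.028) and without control sample 3 (0.037). The replicate block gave 4460 higher and 4543 lower genes. Replicate numbers did not pair the samples: deviations of same-numbered samples correlated at 0.06, 0.04 and -0.07 across genes, and not every sample correlated best with its own number. Alternatives for normalised values, such as other pseudocounts, were not run because the tables hold counts, and DESeq2 gave no list tests. Depth limits scarce genes most, such as MAPK13 with 213 reads over the 6 samples.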

Other observations

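The tests of gene families, of words beside 3′ UTR length, of the joined word CTTCTGAA and of leukocyte transcripts were chosen only after the results were seen.

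A further pair of gene families stood out among 87 that share a symbol stem. Genes of the large subunit of the mitochondrial ribosome (MRPL) were lower, with 36 of 49 falling and 3 rising (median log2 fold change -0.27, camera adjusted p = 0.00069; adjusted p = 0.80 with an estimated correlation). Zinc finger genes of the ZNF stem were higher, with 205 of 451 rising and 53 falling (median 0.23, camera adjusted p = 0.00069; adjusted p = 0.80 with an estimated correlation). Under the other scalings the medians lay between -0.28 and -0.26 and between 0.22 and 0.25. The RPL and RPS stems, which also hold kinase, paralog and readthrough genes, did not pass (22 of 50 rising and 12 falling, adjusted p = 0.59, and 19 of 44 rising and 10 falling, adjusted p = 0.83).

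Most of the tested genes passed the threshold (9014, or 69.5%). The 6 samples can be split into 3 and 3 in 10 ways, too few for a share under 0.05. By edgeR the real split gave 9014 genes and the highest other split 0, so 1 of the 10 splits, the real one itself, gave that many. A mixed split places the group difference within its own groups, so few calls were likely there in any case. Small differences between nearly identical replicates account for part of the count, but 52.0% of the calls still passed against a 1.2-fold change (51.6 to 52.9% with 1 sample left out), just above the bound of 50% set beforehand. GC content and length of the 3′ UTR explained a share of only 0.0045 of the variance of fold changes. The loss of PERK itself, and effects of either siRNA on other transcripts, stay open. So does a difference between cultures, since no label states that the samples of a group came from separate cultures.

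An siRNA can lower other mRNAs through short matches to its seed in their 3′ UTRs, in either group, and the siRNA sequences are not given in the sources used here. Of 14599 words of 7 bases, the one most associated with lower genes was TTCTGAA. Held-out genes carrying it lay lower by a median of -0.0905, short of the difference of 0.1 set beforehand, or by -0.0823 adjusted for 3′ UTR length and GC content. The permutation p of the adjusted difference in means was 1e-05, the smallest the permutations can give. Genes with TTCTGAA in the coding sequence or 5′ UTR alone differed by -0.05 and -0.06. Held-out genes with the joined word CTTCTGAA lay lower than those with neither leading word by a median of -0.22 (448 genes, permutation p = 1e-05 for the difference in means), against -0.06 for the shorter words alone. A seed effect of the PERK siRNA would give this pattern. The joined word was not adjusted for 3′ UTR length or GC content, and its sites outside the 3′ UTR were not compared. Another trait of its carriers therefore cannot be separated from a seed effect. The word most associated with higher genes was AGCCTTA, with a held-out median difference of 0.12, or 0.11 adjusted for 3′ UTR length and GC content (permutation p = 1e-05 for the adjusted means). Genes with it in the coding sequence or 5′ UTR alone differed by 0.09 and -0.06. This met the pattern written beforehand for seed matches of the control siRNA. The coding shift was nearly as large, so another trait shared by genes that carry the word cannot be separated from a seed effect. Whether the rising ZNF genes carry the word was not tested. Sites in the EIF2AK3 mRNA do not tell the words apart, since CTTCTGAA was found there 2 times and AGCCTTA 3 times. These are medians over all carriers, which do not bound the effect on single genes or effects through a regulator. The share of the changes that seed matches account for was therefore not measured.

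The leading pair of higher words was in the 3′ UTR of 40.5% of the 269 held-out genes at least 2-fold higher, against 24.2% expected from held-out genes of like 3′ UTR length. The leading pair of lower words was in 50.6% of the 241 held-out genes at least 2-fold lower, against 33.9% expected. Of the 10 largest rises 6 carried a higher word, but their 3′ UTRs were long (median 3178 bases, against 1388 in all genes searched), and among the 6 of them not used to pick the words 2 carried one, against 1.92 expected from length. Of the 10 largest falls 6 carried a lower word, and among the 7 not used to pick the words 3 did, against 1.77 expected. IL1B carried 1 site of the lower words in its 3′ UTR, and MAPK13 carried 0.

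The lower level of NF-κB-linked genes did not follow the leading pair of lower words in the members' own 3′ UTRs. The 18 members without either word had a median of -1.17 and the 7 with one -0.98, and 28% of members carried a word against 33.6% of all genes. The siRNA seeds are not known, and other words and coding sites in the members were not checked, so sites of those kinds are not excluded. Leukocytes in the control cultures were another candidate, and PTPRC, TYROBP, FCER1G, AIF1 and CSF1R together reached 5.34 to 6.33 CPM of total exon reads in the control samples. That met the level written for this explanation, but CSF1R alone gave 4.62 to 5.51 of it. In a test added afterwards, 8 abundant leukocyte transcripts other than CSF1R were summed (TYROBP, AIF1, LYZ, CD74, HLA-DRA, C1QA, C1QB and CD163). They together reached at most 0.81, which argues against leukocytes. TYROBP and AIF1 were in both panels, and PTPRC and FCER1G were left out of the second. CD14, in neither panel, stood at 9.90 ± 0.40 normalised CPM in the control samples (SD, n = 3). An effect of lower PERK stays open and untested, as does an siRNA effect through a regulator of these genes.

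A hypothesis from the same scan concerns AU-rich words, which mark unstable mRNAs. Held-out genes with TATTTAT in the 3′ UTR and neither leading lower word lay lower by a median of -0.0609 (1154 genes with and 3132 without, permutation p = 4e-05 for the difference in means). The word thus did not merely stand in for that leading pair. Carriers of other lower words, such as TCTGAAT and TTTCTGA, were not removed, so standing in for those is not excluded. That difference was not adjusted for 3′ UTR length or GC content. Over all held-out genes the adjusted difference for TATTTAT was -0.07. PERK siRNA may therefore go with lower levels of some AU-rich mRNAs, a small shift that was noticed and tested on the same data.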
